A study of Mus musculus with 3 samples.

How the data were processed

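Expression was profiled in the R1 mouse embryonic stem cell line on 3 Affymetrix arrays, 1 each for untreated cells, cells treated with BMP4 at 20 ng/ml for 4 h, and cells treated with noggin at 100 ng/ml for 4 h. Total RNA was purified with a Qiagen column kit and labelled with biotin by the array maker's procedure, per the labels' protocols. The authors deposited 1 table of log2 expression values per probe set, computed with RMA per the submitters' processing notes. RMA (robust multi-array average) corrects the background of each array, makes the distributions of the arrays alike by quantile normalization, and summarises the probes of a probe set by median polish. Its version and settings, and the genome build, were not given in the sources used here, so no coordinates are printed.

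The processing sets limits on what can be read from the values. Quantile normalization assumes that most genes are alike, and it would hide a general shift in RNA content. Median polish over few arrays can give many exactly equal values, and 26.1% of probe sets had the same value to 6 decimals on all 3 arrays. In simulated probe sets of 11 probes, a true shift of 0.5 SDs of the probe noise still gave exactly equal summaries in 39.1% of cases, and a shift of 1 SD in 11.9%, so small true differences can appear as 0.00. Arrays have no read depth, and their number limits the precision: with 1 array per condition, biological and technical variation cannot be estimated, and no p-value, SD or standard error between samples is given.

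Probe sets were named with the platform annotation. Of 45101 probe sets, 64 were controls, 34945 were paired with 1 gene symbol (18193 genes), 932 with several and 9160 with none. The Entrez identifiers of 34741 probe sets matched a table of RefSeq genes (assembly GRCm38.p6, used for names only), and 0 symbols were updated. A gene was represented by the probe set with the highest mean over the 3 arrays among those paired with that gene alone. It was kept if its highest value lay above the floor of 3.44, the median of all values, which left 11594 genes, 63.7%. Values were used as deposited, with no further normalization. A probe set not used as a gene's representative entered only the comparison of probe sets within a gene.

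Genes were counted at differences of at least 2-fold, with 1.5-fold as a lower limit. Each of 25 gene lists, fixed before the data were examined, was described by the median difference of its kept members and by the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. A percentile below 2.5 or above 97.5 is spoken of as outside the limits or as on balance higher or lower. The percentile describes these arrays and is not a p-value. Lists with fewer than 5 kept genes have values only. Many genes have exactly equal values, so a list median of 0.00 falls near the middle of the random lists. Some genes are in several lists. If genes varied independently, 1.2 of the 24 lists with a percentile would fall outside the limits in each comparison by chance. The random lists draw genes singly, so a list whose members vary together can fall outside more often.

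The genes named in the text were taken by a rule fixed before the data were examined. It takes, for each comparison with the untreated array, the 12 kept genes with the largest difference above 0 and the 12 with the largest below 0, and for BMP4 minus noggin 6 and 6. It leaves out symbols that are clone or model names, and genes with another probe set above the floor whose difference has the opposite sign. It adds every list member that differed at least 2-fold in any comparison, Id1, Id2, Id3, Smad6, Smad7, Pou5f1, Sox2 and Nanog whatever their values, and, for a list that is described, the 2 members with the largest differences in each direction, of which the text prints some. Other genes are named with a remark that they were chosen after their values were seen. In a simulation on the 11594 genes, BMP4 values were replaced by untreated values plus differences redrawn with random sign from noggin minus untreated. The fold sizes given to 200 genes were recovered by the computation. That checks the arithmetic only and says nothing of detection, since a fixed size limit was used. Of 200 random lists of 18 unchanged genes in that simulation, 11 fell outside the limits. Its genes varied independently by construction, unlike those of the real lists.

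Technical spread was read from the control probe sets and from the SD of the differences among probe sets of a gene. The correlation of the comparisons that share the untreated array was set beside that of 100 simulated sets of 3 arrays with no effect and the same spread on every array. The alternatives were 4 other rules for the floor, the mean over all probe sets of a gene, probe sets with the plain suffix alone, probe sets as units, loess-corrected (span 0.3) or median-centred differences, other size limits, and for lists the mean over members and lists without their most different member or without members of other lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.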

Results

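Gene expression was measured in R1 cells, an established mouse embryonic stem cell line, in the undifferentiated state. The cells were left untreated, treated for 4 h with BMP4 at 20 ng/ml, or treated for 4 h with noggin at 100 ng/ml. For the untreated cells the sample labels used here gave no time. BMP4 is a bone morphogenetic protein that signals through receptor-activated SMAD transcription factors, and noggin is a secreted antagonist that binds BMPs and keeps them from their receptors. Each condition was represented by 1 Affymetrix array, 3 arrays in all. No value therefore has a replicate error, no test was made, and differences are described by their size on these arrays, whose number limits the precision. Values are log2 RMA expression values, and a difference of 1 is a 2-fold difference.

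The arrays carried 45101 probe sets, and 11594 genes had a value above the floor of 3.44 on at least 1 array. The median value over all probe sets was 3.45 on the untreated array, 3.45 on the BMP4 array and 3.43 on the noggin array. Across probe sets, which are not independent replicates, Pearson's r between arrays lay between 0.998 and 0.999. The difference from the untreated array was within 0.5 in either direction for 99.6% of genes with BMP4 and for 99.8% with noggin. Probe sets of the same gene gave differences with a within-gene SD of 0.13 for BMP4 minus untreated, 0.11 for noggin minus untreated and 0.16 for BMP4 minus noggin, over 13666 probe sets of 5139 genes. The 24 probe sets for the poly-A spikes, transcripts added to the RNA before labelling, were all lower on the BMP4 array than on the untreated array, with a median difference of −0.63. On the noggin array 23 of the 24 were lower, with a median difference of −0.18. The 18 probe sets for the hybridisation spikes, added after labelling, had median differences of 0.01 and −0.01. The 3′ probe set exceeded the 5′ probe set of Actb by 0.32 on the untreated, 0.21 on the BMP4 and 0.37 on the noggin array, and that of Gapdh by 0.06, 0.09 and 0.10. For Tfrc the excess was larger, 1.51 on the untreated, 1.38 on the BMP4 and 1.88 on the noggin array, where its 5′ probe set measured 5.90 against 6.50 on the untreated array.

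BMP4-treated cells were first compared with untreated cells, which asks how transcripts of undifferentiated cells differ after 4 h of added BMP4. Id1, Id2 and Id3, whose proteins bind basic helix-loop-helix factors and block their access to DNA, stood furthest from the untreated array. Id2 measured 8.90 with BMP4 and 4.80 without it, a 17.1-fold higher value. Id3 was 12-fold higher, at 9.16 against 5.58, and Id1 was 6.79-fold higher, at 11.54 against 8.78. Msx2, a homeobox gene of the BMP pathway, was 2.92-fold higher, whereas Lefty1, which encodes a secreted antagonist of Nodal, was 2.14-fold lower, at 7.54 against 8.64. The transcripts of the core pluripotency factors differed little: Pou5f1 measured 11.53 with BMP4 and 11.31 without, Nanog was higher by 0.14, and Sox2 measured 11.16 on both arrays.

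Of the 11594 genes, 11 were at least 2-fold higher with BMP4 and 1, Lefty1, was at least 2-fold lower. At a limit of 1.5-fold the counts were 26 and 6. Besides Id1, Id2, Id3 and Msx2, the genes past 2-fold included a pair of MAP kinase phosphatases, Dusp9 with a difference of 1.33 and Dusp5 with 1.11. Malat1, a nuclear long non-coding RNA, was higher by 1.24, Coch, a secreted protein of the extracellular matrix, by 1.22, and Ccn2, the connective tissue growth factor, by 1.09. The 7 probe sets of Malat1 above the floor ranged from 0.00 to 2.34. The remaining 2 of the 11 were Hnrnpu at 1.46 and Pggt1b at 1.11, which were chosen for mention after their values were seen; for both, at least 1 other probe set of the gene had a difference below 0. When all probe sets of a gene were averaged, Hnrnpu, Malat1 and Pggt1b no longer passed 2-fold, which left 9 of the 12 genes. Just under the limit were Gata2 at 0.99, a zinc finger factor of blood and trophoblast development whose other probe set gave 0.27, Sox7 at 0.99, an endoderm and endothelial factor, and Mpst at 0.97, a mercaptopyruvate sulfurtransferase.

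Among the genes with lower values with BMP4, Bgn (biglycan, a matrix proteoglycan) had a difference of −0.85 and Ackr3 (an atypical chemokine receptor) of −0.82. The difference was −0.71 for Taf7l, −0.67 for Anxa1 (annexin A1) and −0.66 for Foxd3, a forkhead factor of pluripotent cells. Smaller differences were found for Pdgfc and Fgfbp1 at −0.57 each, S100a4 and the BMP co-receptor gene Hjv at −0.55 each, Slc44a2 at −0.52, and Plec (plectin) at −0.51. For Bgn and Slc44a2, another probe set above the floor gave exactly 0.00, and the second probe sets of Plec and Pdgfc gave −0.07 and −0.22. Hjv was below the floor with BMP4, at 3.38.

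Counted by probe set, 30 of the 22755 probe sets above the floor were at least 2-fold higher with BMP4 and 1 was at least 2-fold lower. Some of these belonged to 16 genes that had several probe sets above the floor, and in 4 of the 16, Aspm, Dusp9, Id2 and Malat1, another probe set was also at least 2-fold higher. The probe sets of Id2 gave 4.10 and 4.71, and those of Dusp9 1.07 to 1.33. In the other 12 genes no second probe set reached 2-fold, and for Hnrnpu the other 4 lay between −0.07 and 0.03. For 2 of the 16, Zfp292 and Armc9, the highest probe set was below the floor on the untreated array, at 2.49, so its difference is taken against a value in the background. The genes of this group that the rule for names does not take were chosen after their values were seen.

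**Figure D1:**
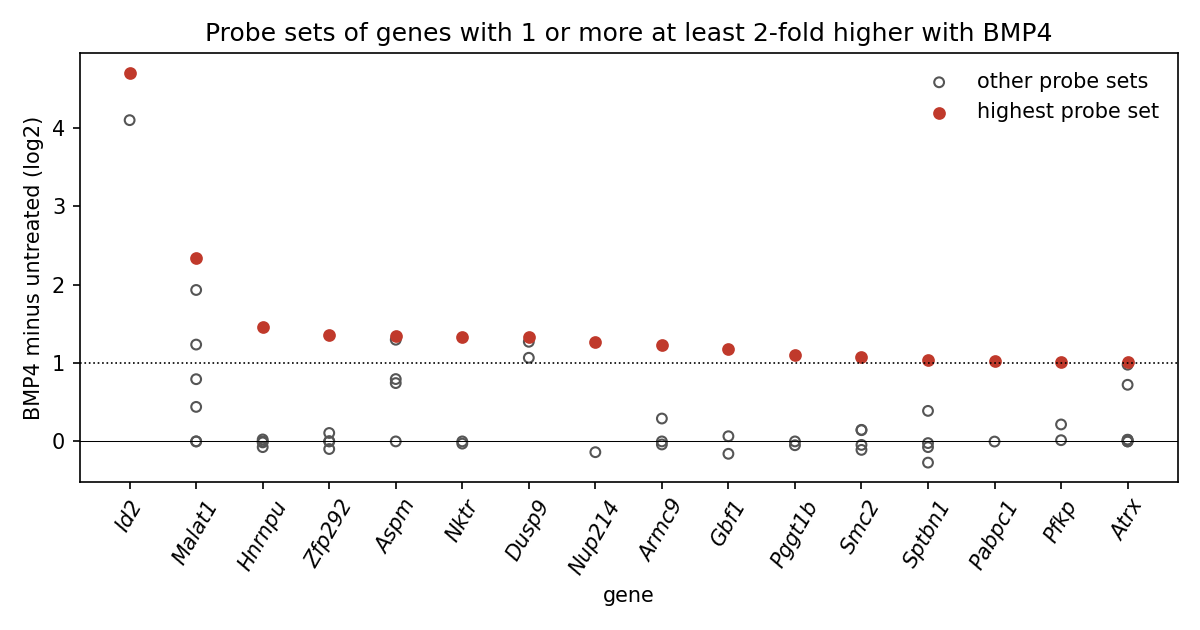
Difference between BMP4 and untreated (vertical axis, log2) of every probe set above the floor, for the 16 genes with several probe sets of which at least 1 was 2-fold higher with BMP4 (dotted line); filled points are the highest probe set of each gene and open points the others. Both probe sets of Id2 lie above 4, and for 12 of the 16 genes no other probe set reaches 2-fold.

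**Figure D2:**
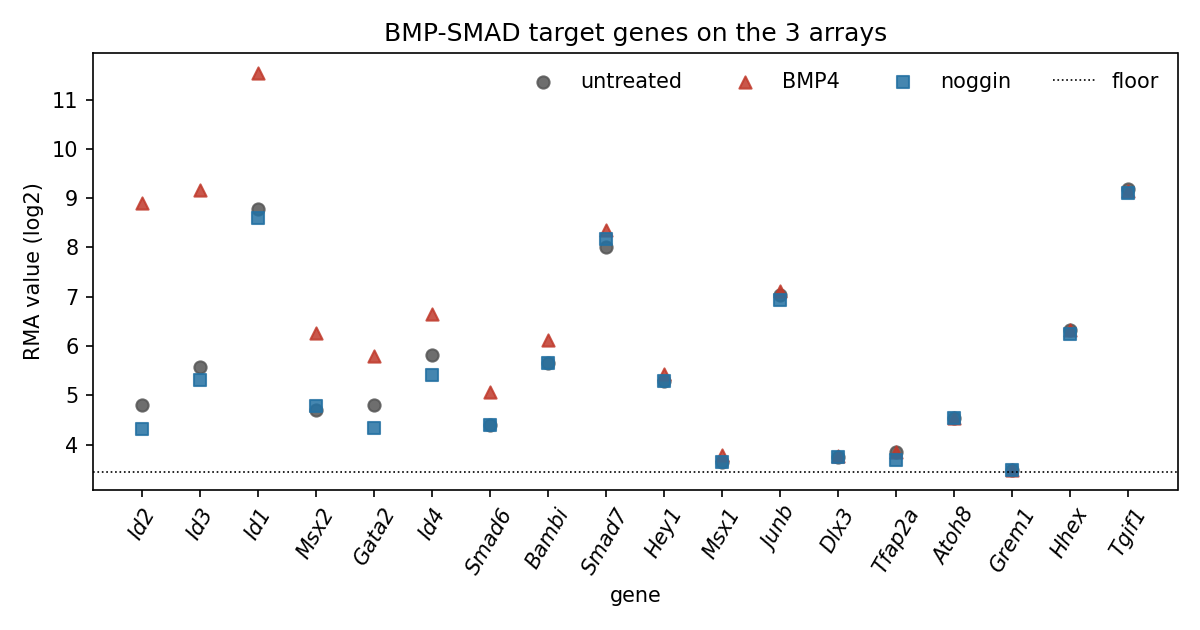
Log2 RMA values of the 18 measured BMP-SMAD target genes (horizontal axis) on the untreated (circles), BMP4 (triangles) and noggin (squares) arrays, 1 array each, ordered by the difference between BMP4 and untreated; the dotted line is the floor of 3.44. The BMP4 values of Id2, Id3 and Id1 are 8.90, 9.16 and 11.54, while those on the untreated and noggin arrays lie close together.

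The list of BMP-SMAD target genes had 18 members above the floor out of 23, and 13 were higher with BMP4, 1 was lower and 4 were exactly equal. Its median difference was 0.25, at percentile 100 of random lists of genes of matched level, whose central 95% ran from −0.02 to 0.00. After the 3 Id genes and Msx2, the larger differences were those of Gata2, Id4 at 0.84, the inhibitory SMAD gene Smad6 at 0.67 and the pseudoreceptor gene Bambi at 0.46. Smad7 was higher by 0.34, and Tgif1, at −0.06, was the member below 0. Among BMP ligands, receptors, SMADs and antagonists, 7 of 20 were higher and 4 lower; Bmp4 itself differed by −0.26 and Smad1 by −0.12.

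Of 12 primitive streak and mesoderm genes, 7 were higher and 1 lower, with a median of 0.09 at percentile 100; Gata2 and Snai1, at 0.57, were highest, and Kdr was at −0.12. That median was 0.00 with no floor (26 genes, percentile 50.1) and without members of other lists (percentile 53). Of 14 LIF-STAT3 target genes, 8 were higher and 3 lower, with a median of 0.02 at percentile 99.4, from Socs2 at 0.39 and Klf4 at 0.13 down to Mras at −0.19 and Gbx2 at −0.20. Its median was 0.00 at percentile 60.7 without members of other lists, its mean lay at percentile 90.9, and with probe sets averaged its median lay at percentile 88.9. A further 3 lists had medians below 0. Of 14 germ cell genes, 11 were lower and 1 higher, with a median of −0.05 at percentile 0.97; Dazl was at −0.41 and Sycp3 at −0.35, against Tfap2c at 0.38, and the percentile was 3.47 without Dazl and 4.57 without members of other lists. Of 8 Wnt target genes, 6 were lower and 1 higher, with a median of −0.07 at percentile 1.13, and Notum (−0.36) and Znrf3 (−0.26), both feedback inhibitors of Wnt signalling, were lowest; with probe sets averaged the percentile was 2.99. Of 18 fibroblast markers, 10 were lower and 1, Thy1 at 0.02, was higher, with a median of −0.05 at percentile 0.08; S100a4 was at −0.55 and Postn, below the floor on both arrays, at −0.32, and with no floor the median was 0.00 at percentile 50.2. These 5 lists and the poly-A spikes differed on the same pair of arrays.

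The other 18 lists with at least 5 measured genes lay within the limits that set a list apart. Of 26 pluripotency genes, 10 were higher and 13 lower, with a median of −0.0026 at percentile 16.1, and their differences ran from Prdm14 at −0.28 and Nr5a2 at −0.27 to Fgf4 at 0.19 and Pou5f1 at 0.22. The Nodal-activin target genes went both ways, 5 higher and 5 lower: Lefty1 at −1.10 and Lefty2 at −0.38 were lowest, and Skil at 0.57 and Eomes at 0.46 were highest. The list's median was 0.0030 at percentile 90.6 and its mean −0.01; without members of other lists, which left 5 genes, the median was −0.20 at percentile 0.040, and without Lefty1 it was 0.03 at percentile 98.0, both outside the limits. FGF-ERK feedback genes had 6 members higher, with Dusp5 at 1.11 and Spry4 at 0.48, and 7 lower, with Egr1 at −0.21 and Spred1 at −0.17; the median was −0.03 at percentile 6.85 and the mean 0.11 at percentile 99.7, and the median was −0.06 at percentile 1.40 without Dusp5 and 0.02 at percentile 98.2 without members of other lists. Median and mean also had opposite signs for the extracellular matrix and TGF-beta responsive genes, at −0.0065 (percentile 15.6) and 0.10 (percentile 99.3), with Ccn2 and Skil highest and Jag1 (−0.46) and Fn1 (−0.16) lowest. In the endoderm list, 6 of 17 were higher and 6 lower; Sox7 and Gata6, at 0.52, stood above, and the laminin gene Lama1, at −0.17, and the collagen gene Col4a2, at −0.13, below. The endoderm list lay outside the limits on opposite sides by its mean of 0.08 and, with a floor at the 75th percentile, by a median of −0.08. Gadd45b was 0.66 higher and Gadd45a 0.22 higher among the 19 cell cycle inhibitors and p53 targets, with Cdkn1b at −0.17 and Zmat3 at −0.13. The median was 0.00 for 14 lists, at percentiles between 52.3 and 62.2: the last 2 named, BMP ligands and receptors, primed epiblast, neuroectoderm, trophoblast, immediate-early, Notch target, cell cycle, unfolded protein and amino acid response, heat shock, cholesterol synthesis, hypoxia and glycolysis, and interferon response genes. Of these, the BMP ligand and immediate-early lists lay above the limits by their means, 0.05 and 0.09, the latter also with the higher floor, at 0.08. If genes varied independently, 1.2 of the 24 lists would pass the limits in a comparison by chance, and more would if list members vary together. The BMP-SMAD list passed them under all 7 alternative settings.

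Noggin-treated cells were compared with untreated cells, which asks how transcripts differ after 4 h under a BMP antagonist. No gene was 2-fold higher or lower. Several of the genes that were higher with BMP4 were lower with noggin: Id2 measured 4.31 against 4.80 without treatment, a difference of −0.49, and Gata2 differed by −0.47, Id4 by −0.40, Id3 by −0.26 and Id1 by −0.19. Smad6 had exactly the same value, 4.40, and Msx2 and Smad7 were higher by 0.06 and 0.16. Pou5f1 was equal at 11.31, and Sox2 and Nanog differed by −0.04 and −0.06. The second probe set of Id2 gave −0.05, that of Gata2 −0.11 and that of Smad7 −0.19, opposite in sign to its first. The other probe sets of Id4 gave −0.41 and −0.22.

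At a limit of 1.5-fold, 1 gene was higher with noggin and 8 were lower. Of the 8, 6 were taken by the rule for named genes: Trnp1, a regulator of progenitor cells in the brain, at −0.82, Bcan (brevican) at −0.68, Slc44a2 (a choline transporter-like protein) at −0.67, Hoxd9 and Zfp758 at −0.62 each, and Car14 (carbonic anhydrase 14) at −0.59. The other 2, outside the rule and chosen for mention after their values were seen, were Taf15 at −0.71, whose second probe set gave 0.09, and the clone-named gene 1700001G11Rik at −0.69. Below the limit followed Zfp935 at −0.58, Neurog3, a proneural factor, at −0.57, Hjv at −0.56, Rep15 and the paraxial mesoderm factor Mesp2 at −0.54, and Rad51b at −0.53. Bcan, Zfp758 and Car14 had untreated values of 3.45, 3.60 and 3.55, near the floor, and noggin values of 2.77, 2.98 and 2.97, below it. Neurog3, Hjv, Rep15 and 1700001G11Rik were also below the floor with noggin, at 3.28, 3.37, 3.30 and 3.33, and Zfp935 was below it on both arrays, at 3.01 and 2.43. The 5th percentile of all values was 1.60 on the noggin array and 1.82 on the untreated array. The 1 gene 1.5-fold higher was Fam160a1 at 0.60, whose untreated value of 2.91 was below the floor and whose noggin value was 3.51. Other higher genes were Tigd5 at 0.50, the basic leucine zipper factor Nfil3 at 0.47, the centrosomal gene Cep135 at 0.46, Nacc1 at 0.43, Itsn2 at 0.42, Dgkq and the potassium channel gene Kcnd1 at 0.41, Retn (resistin) at 0.40, Cdc42bpa at 0.37, and Nckap5l and Slc17a5 at 0.36. For Slc44a2, Tigd5, Itsn2 and Cdc42bpa another probe set above the floor gave exactly 0.00.

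**Figure D3:**
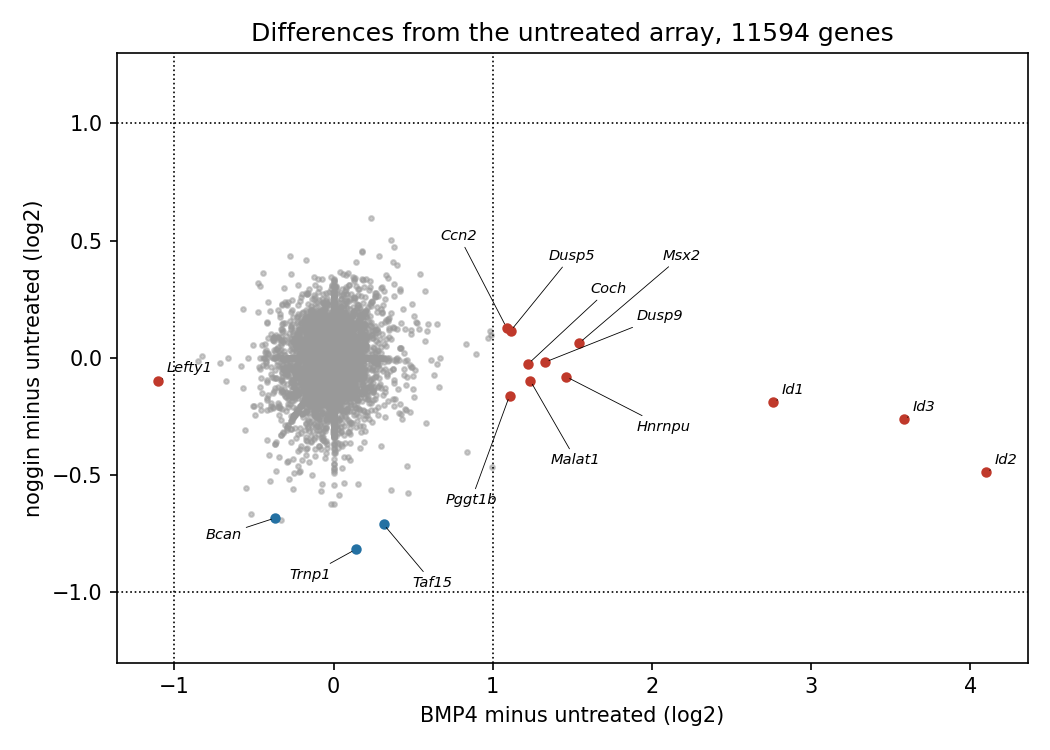
Difference between BMP4 and untreated (horizontal axis, log2) against the difference between noggin and untreated (vertical axis, log2) for 11594 genes, 1 point per gene and 1 array per condition; dotted lines mark 2-fold. Red points are the 12 genes past 2-fold with BMP4, blue points are Trnp1, Taf15 and Bcan, at −0.82, −0.71 and −0.68 with noggin, and no gene lies beyond the horizontal lines.

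Of the 18 BMP-SMAD target genes, 10 were lower with noggin, 2 were higher and 6 were equal, with a median of −0.05 at percentile 0.34 of random lists, whose central 95% ran from −0.02 to 0.00. Without Id2, the member with the largest difference, the median was −0.0094 at percentile 5.19, and with no floor it was −0.0095 at percentile 5.37. LIF-STAT3 target genes were lower in 11 of 14 cases and higher in 1, with a median of −0.07 at percentile 0.090; Fos was at −0.33, Socs3 at −0.25 and Tfcp2l1 at 0.05. That list passed the limits under every alternative setting tried. On the same pair of arrays 23 of the 24 poly-A spike probe sets were lower with noggin, by a median of −0.18, and the 3′ minus 5′ value of Tfrc was 1.88 against 1.51. Of 9 primed epiblast genes, 6 were lower and 2 higher, with a median of −0.06 at percentile 1.26; Pou3f1 and Fgf15 were both at −0.36, and Cldn6 was at 0.18; with probe sets averaged the percentile was 5.51, and without members of other lists 3.87. Of 14 germ cell genes, 9 were lower and 2 higher, with a median of −0.05 at percentile 0.91, including Mael at −0.20 and Sycp3 at −0.19, with Dazl at 0.08; 3 alternatives gave percentiles from 3.02 to 3.66. BMP ligands, receptors, SMADs and antagonists had 10 of 20 members higher and 3 lower, with a median of 0.0099 at percentile 99.5; Eng (endoglin) was at 0.21 and Bmp7, below the floor with noggin, at −0.34. Its median was 0.00 with no floor and with probe sets averaged, at percentiles 57.8 and 65.0, and its mean lay at percentile 93.6.

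Of the other lists, neuroectoderm genes had 7 of 14 members lower and 3 higher, with a median of −0.02 at percentile 4.55; Six3, below the floor with noggin, was at −0.39 and Ncam1 at −0.35, and Nes (nestin) at 0.17. With no floor its median was −0.06 at percentile 1.31, outside the limits, and without Six3 it was 0.00, inside them. Heat shock genes had a median of 0.01 at percentile 97.1, and 97.9 with no floor, Nodal-activin target genes of −0.02 at percentile 15.0, and Wnt target genes of −0.02 at percentile 6.58. Immediate-early genes had a median of −0.0062 at percentile 9.12, or −0.09 at percentile 0.445 with a floor at the 75th percentile, and cholesterol synthesis genes of −0.0018 at percentile 29.7. In the remaining 13, fibroblast markers included, the median was 0.00 at percentiles between 52.1 and 66.6. Of these, the endoderm and extracellular matrix lists lay above the limits with the higher floor, both at 0.07, and the endoderm and Notch lists without members of other lists, at 0.0040 and 0.05. Among the 26 pluripotency genes, 10 were higher and 12 lower, the highest being Fgf4 at 0.10; Lin28a was lowest at −0.57, but its second probe set gave 0.08.

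BMP4-treated and noggin-treated cells were then compared directly, without the untreated array, as the contrast between an added BMP and a BMP antagonist. Id2 was 24.0-fold higher with BMP4 than with noggin, Id3 14.4-fold, Id1 7.74-fold and Id4 2.36-fold. Msx2 was 2.79-fold higher, Gata2 2.76-fold and Dusp9 2.54-fold. In the opposite direction, Lefty1 was 2-fold lower with BMP4, at 7.54 against 8.55. The largest differences below 0 after it were those of Bgn and Ackr3, both at −0.83, the deubiquitinase gene Usp17la at −0.80, and Fgfbp1 and the ankyrin gene Ank2, both at −0.77. Ank2 was below the floor with BMP4, at 2.88, and measured 3.65 with noggin.

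At least 2-fold differences were found for 13 genes higher and 1 gene lower, and at 1.5-fold for 44 and 16. Besides those named, the genes past 2-fold were Malat1 at 1.33, Coch at 1.25 and Zfp935 at 1.05, and, chosen for mention after their values were seen, Hnrnpu at 1.54, Pggt1b at 1.27 and Taf15 at 1.02. When all probe sets of a gene were averaged, 9 genes passed 2-fold, all among the 14, and Gata2, Id4, Hnrnpu, Pggt1b and Taf15 did not. Zfp935 had values of 3.48 with BMP4 and 2.43 with noggin, around the floor.

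Among the 18 BMP-SMAD target genes, 16 were higher with BMP4 than with noggin, 0 were lower and 2 were equal, with a median of 0.18 at percentile 100. The order BMP4 above untreated above noggin was found for 7 of the 18, and the reverse order for 0. LIF-STAT3 target genes were higher in 10 of 14 cases and lower in 1, with a median of 0.13 at percentile 100; Socs2 was at 0.56 and Fos at 0.33, and Mras at −0.19; with probe sets averaged the median was 0.04 at percentile 94.8. Primitive streak and mesoderm genes were higher in 6 of 12 cases and lower in 1, with a median of 0.07 at percentile 99.3; after Gata2, Mesp2 was at 0.69 and Eomes at 0.57, and the median was 0.00 without Gata2 (percentile 46.9), with no floor (35.9) and without members of other lists (43.5). Fibroblast markers were lower in 10 of 18 cases and higher in 1, with a median of −0.12 at percentile 0.00, with Postn at −0.55 (below the floor with BMP4), Fn1 (fibronectin) at −0.44 and Thbs1 at 0.06. The poly-A spikes were lower by a median of −0.46 between the same arrays. Wnt target genes were lower in 5 of 8 cases and higher in 2, with a median of −0.09 at percentile 0.70; Notum was at −0.27, Apcdd1 at −0.26 and Ccnd1 at 0.07, and with no floor the median was 0.00 at percentile 37.5. The BMP-SMAD list and the fibroblast list passed the limits under every alternative setting tried.

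The 19 lists inside the limits included germ cell genes, with a median of −0.03 at percentile 5.77 (1.70 with the higher floor and 1.25 with probe sets averaged), hypoxia and glycolysis genes, with −0.0049 at percentile 14.3, FGF-ERK feedback genes, with 0.0091 at percentile 90.3 (mean 0.14, above the limits), and Nodal-activin target genes, with 0.02 at percentile 87.7 (−0.20 at percentile 0.23 without members of other lists). Heat shock genes had a median of 0.02 at percentile 88.9 and a mean of −0.03, so that the signs differed. The other 14 had a median of 0.00 at percentiles between 45.0 and 52.5; of these, the primed epiblast and immediate-early lists lay above the limits by their means, 0.14 and 0.11, and the endoderm list below them with the higher floor, at −0.13. The 2-cell-like list had only 2 measured genes, Zfp352 and Eif1a, whose differences were −0.21 and −0.16 with BMP4 and 0.08 and −0.01 with noggin, each against untreated.

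The 3 values spanned at least 1 for 16 genes, and the untreated array held the middle value in 12 of them, or 75% (exact 95% binomial confidence interval 47.6 to 92.7%, which treats genes as independent). Exchangeable arrays would give 33.3%, and genes that differed on the BMP4 array alone would give 50%, which lies inside the interval. The noggin array was in the middle for 4 genes and the BMP4 array for 0. At a span of at least 0.5, where 121 genes had no tie, the untreated array was in the middle for 83, or 68.6% (59.5 to 76.7%, which lies above 50%), the noggin array for 26 and the BMP4 array for 12. Genes on an array are not independent, so neither interval is a test of opposite responses. The 3′ minus 5′ values of Actb and Tfrc also had the untreated array in the middle, whereas that of Gapdh was lowest there. A difference in RNA quality between the arrays therefore cannot be told apart from opposite responses. Across genes, the differences BMP4 minus untreated and noggin minus untreated had a Pearson's r of 0.088 and a covariance of 0.0011. They share the untreated array, and simulated arrays with no effect gave an r of 0.50 and a covariance of 0.0079. The simulation gave every array the same spread, so an r near 0.50 followed by construction. The observed covariance lay below the simulated one by −0.0069. The real differences had unequal variances, 0.0156 for BMP4 minus untreated, 0.0094 for noggin minus untreated and 0.0229 for BMP4 minus noggin. A smaller spread on the untreated array would also lower the covariance, so this gap cannot be read as opposite responses. The single control could not be split.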

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

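The 3 tests described here were chosen after the result was seen. The probe sets below did not represent a gene in the comparisons above and belong to no gene past 2-fold there, so they did not enter the counts of genes, and each gave at least 2-fold more signal on the BMP4 array than on the untreated array while none did on the noggin array.

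Among the 14 such probe sets, 2 had no symbol: 1428670_at was higher by 1.38 and 1456319_at by 1.20. The spindle gene Aspm had 2 such probe sets, at 1.35 and 1.297, and 1 each was found for the condensin gene Smc2 at 1.08, Nktr at 1.33, the nuclear pore gene Nup214 at 1.26 and the chromatin remodeller gene Atrx at 1.01. The others were Gbf1 at 1.18, the spectrin gene Sptbn1 at 1.04, the poly-A binding protein gene Pabpc1 at 1.03 and the phosphofructokinase gene Pfkp at 1.01. For the zinc finger gene Zfp292 at 1.35 and for Armc9 at 1.23, the untreated value was 2.49, below the floor of 3.44, and the probe sets passed the floor on the BMP4 array, at 3.84 and 3.72, so these sizes rest on values in the background. The brightest probe set of each of these genes, which represented it in the comparisons, differed by between −0.14 (Nup214) and 0.07 (Gbf1), with Aspm at 0.00 and Smc2 at −0.04.

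The pattern weighed is that 16 genes with several probe sets had at least 1 that was 2-fold higher with BMP4. The highest probe set of each gene was set against its others, which are lower by that choice. Genes with only 1 probe set above the floor, Id1, Id3 and Msx2 among them, could not enter. A higher level of the whole transcript would lift the other probe sets too, but their median difference over the 16 genes was 0.000572, with an upper quartile of 0.24 against 0.62, which is 0.5 of the median for the highest probe sets (without Zfp292 and Armc9, a choice made after seeing the data, 0.0094, 0.49 and 0.61). That argues against it as the general account for these 16 genes, though Id2 and Dusp9 go that way in every probe set above the floor. Malat1 and Aspm, with at least 1 other at 2-fold, and Atrx, with a second at 0.98, do so only in part. Malat1, Aspm and Atrx each also had a probe set at exactly 0.00. Noise of single probe sets would give as many lower as higher values, and 1 probe set was at least 2-fold lower against 30 higher. The 30 include probe sets of Id1, Id2, Id3 and Msx2, so they are not a count of probe sets that stood alone. In 12 of the 16 genes (10 without Zfp292 and Armc9), 1 probe set alone was at least 2-fold higher. The lower probe set was that of Lefty1, which had no other above the floor. These narrower counts also differ from the equal counts that such noise would give. Differences in RNA handling or labelling of the BMP4 array cannot be told apart from the treatment, because the poly-A spikes differed by a median of −0.627 and each condition has 1 array; a change in transcript ends or retained introns with BMP4 may also account for it and was not tested.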

How the results depend on the processing

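All alternatives in this part were fixed before the data were examined. Counts at 2-fold were within 1.5 times the reported count in 23 of 33 cases. For BMP4 minus untreated (12 genes), 31 probe sets passed when probe sets were the units, and 32 genes at 1.5-fold. At 3 local robust SDs, 271 genes passed (127 higher, 144 lower). With plain-suffix probe sets alone, Id1 and Id2 had none above the floor, so they dropped out without being measured. Malat1 did not pass there, because its brightest plain-suffix probe set had a difference of 0.00. For noggin minus untreated (0 genes), 9 passed at 1.5-fold and 146 at 3 local robust SDs (49 higher, 97 lower). For BMP4 minus noggin (14 genes), 9 passed with the mean of all probe sets, 9 with plain-suffix probe sets alone, 42 as probe sets, 60 at 1.5-fold and 276 at 3 local robust SDs (150 higher, 126 lower). The cause was not tested, except that a lower limit or more units passes more by construction. Genes with no plain-suffix probe set above the floor, Id1, Id2, Gata2 and Zfp935 among them, likewise drop out of that setting by construction. The BMP-SMAD list stayed outside the limits in 19 of 21 cases; for noggin minus untreated its median was −0.0095 with no floor and −0.0094 without its most different member, both inside, and the cause was not tested. No result that was outside the limits or past 2-fold changed direction. Of the 16 list comparisons outside the limits, 4 stayed there throughout. Lists inside the limits came to lie outside in 25 cases. For BMP4 minus untreated, the Nodal-activin median was −0.20 and below the limits without members of other lists, and 0.03 and above them without its most different member; the FGF-ERK list lay above the limits by its mean (0.11) and below them without its most different member (−0.06), and the endoderm list above by its mean (0.08) and below with a floor at the 75th percentile (−0.08). Averaging the probe sets of a gene took Malat1 to 0.96 with BMP4, and Gata2 to 0.92 and Id4 to 0.90 for BMP4 minus noggin. The untreated array held the middle value most often in all 3 alternatives. A pseudocount for linear values was not run, since the values are log2. No paired analysis was possible because each condition has 1 array, and no array could be left out. For genes near the floor of 3.44, background limits what a difference can show.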

Other observations

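Genes with differences in the same direction under both treatments, chosen for mention after their values were seen, are described first. The placental homeobox gene Rhox9 measured 4.46 on the untreated array and 4.09 on both others, a difference of −0.37. The neural adhesion gene Ncam1 differed by −0.42 with BMP4 and −0.35 with noggin, Slc44a2 by −0.52 and −0.67, and Hjv by −0.55 and −0.56. Ccn1, a matrix-associated immediate-early gene, was higher by 0.34 with both, the Notch target Hes1 by 0.49 and 0.23, and Retn by 0.40 with both. These differences share the 1 untreated array, so a deviation of that array would give the same picture. Rhox9, Ccn1 and Retn had exactly equal values on the BMP4 and noggin arrays, as did 32.9% of the kept genes. Such ties can come from the processing.

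Of 25 cell cycle genes, 11 were higher and 7 lower with BMP4, and as many with noggin, and the largest difference was that of Mki67 at −0.21 with BMP4 and 0.24 with noggin. The heat shock gene Hspa1b was at −0.27 with BMP4 and 0.00 with noggin, and the unfolded protein response gene Creld2 at −0.23 and 0.01. These stress genes were chosen for mention after their values were seen.

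For the patterns that follow, the test of rounding was chosen after the result was seen. Over all probe sets, 26.1% (11750) had exactly the same value on all 3 arrays. The tied values are written to 6 or more decimals in 100% of cases, which argues against rounding. When unchanged probe sets were simulated and summarised by median polish over 3 arrays, 43.3% tied, while with 4, 5, 7 or 9 arrays at most 10.3% did. Median polish run on these 3 arrays alone could therefore give such ties. Some values also recur across genes, such as 4.398647 for Smad6, Fos and Tex101 on the untreated array. The simulation drew continuous probe values, so it does not cover ties from probe values that recur. No biological explanation was tested.

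The BMP-SMAD target genes that were at least 1.5-fold higher with BMP4 (Id1, Id2, Id3, Id4, Smad6, Msx2 and Gata2) were lower with noggin in 5 of 7 cases, with a median of −0.26. A level-dependent shift of the noggin array should vanish on loess correction, but the corrected median stayed at −0.26, at percentile 0.00 of random lists of matched level. Without Id2 the median was −0.23. Some BMP signalling in the untreated cultures may account for the pattern, as an untested hypothesis, but a difference in handling of the single noggin array stays open too, and these arrays cannot decide between them.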
